A study of Mus musculus with 6 samples.

How the data were processed

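RNA was measured in 6 bulk libraries of sorted mouse intestinal stem cells, 3 treated with INT-777 and 3 with DMSO. Per the submitters' processing notes, reads were checked with FastQC and aligned with STAR 2.73a, and edgeR 3.24.3 was used; the notes name the builds GRCm38 and mm10, and the annotation version is not given in the sources used here. The deposited files hold whole-number counts of read pairs per gene as STAR writes them, with no normalisation, 1 file per library. The column that ignores strand was used, because the strand columns each held close to equal shares (50.1 to 50.6% in the first of them) and the rule fixed beforehand asked for 80%. Reads from genes that overlap on opposite strands are therefore ambiguous. Each file lists 54838 Ensembl gene IDs, of which 54809 matched GENCODE M21 and 29 did not; 108 symbols are carried by more than 1 ID.

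Between 60717640 and 63604301 read pairs per library entered the alignment. Lines that are not genes stayed out of library sizes and tests: unmapped pairs were 10.3 to 11.3%, multimapping pairs 5.96 to 6.31%, pairs on no gene 3.32 to 3.83% and ambiguous pairs 4.35 to 4.54%, which left 74.5 to 75.6% assigned to genes. The 10 most abundant genes took 6.76 to 8.42% of the assigned pairs and mitochondrial genes 5.13 to 5.92%. At this depth a gene of 1 CPM has some 46 to 48 counts per library.

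Tests, samples, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were filtered with filterByExpr by group, which left 15998; library sizes were scaled with TMM; and INT-777 was compared with DMSO by the edgeR quasi-likelihood test with robust fitting, two-sided, with treatment as the single term and a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 change over the square root of F. CPM values (counts over library size in units of 1e6) are TMM-scaled means with SD over 3 libraries. Genes that differ between days were tested with the F-test of the day terms in a model of treatment and day.

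Of 39 gene lists fixed beforehand from general knowledge, the 38 with at least 5 tested members were tested with camera (limma, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 38. Camera with an estimated correlation and the fry test were run beside it. Members were also counted after adjustment over the list alone.

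Named genes are Gpbar1 and Lgr5, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1, an official symbol and the same direction on all 3 days, the 2 members of smallest p in each primary list, and the 3 of smallest p in each other list that was called. The result of 1 gene that this rule names is not reported. Other genes named in the text are further list members, chosen after their values were seen.

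The labels state that a replicate number marks a shared day, which pairs the libraries. Deviations from the group mean correlated at 0.329, 0.369 and 0.632 between the libraries of days 1, 2 and 3; INT-777 replicate 1 correlated slightly more with DMSO replicate 2 (0.336) than with its own, and correlations of day 3 with the other days lay between −0.435 and −0.487. The common biological coefficient of variation was 0.149 without the day block and 0.048 with it. The alternatives were the day block, other scaling factors, DESeq2 and limma-voom in place of edgeR, other low-count filters, the counts of 1 strand, RNA integrity as a covariate, a GC offset together with the block, other thresholds, and leaving out each library and each day.

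The tests were tested on simulated counts drawn for each gene on its own from the fitted means and dispersions, in which 100 genes each changed 1.5-fold and 2-fold. Without the block edgeR recovered 62% and 86% with 7 false calls, DESeq2 69% and 91% with 18, and limma-voom 62% and 87% with 8. With the block edgeR recovered 96% and 100% with 7 false calls, and DESeq2 87% and 99% with 0. The simulated days were independent, with the same treatment effect on each. The false calls there cannot show whether the blocked calls in the data, where days 1 and 2 were nearly alike, are too many. The test of days recovered 94% and 100% with 9 false calls. Camera with the preset correlation recovered the simulated list of 25 genes, shifted 1.23-fold, and called 1 list falsely. The simulated genes were independent. This therefore does not test the list calls where members vary together, as goblet markers did (estimated correlation 0.98). With an estimated correlation it recovered the list without the block and not with it.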

Results

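The experiment asked which genes respond in intestinal stem cells when TGR5 is stimulated. TGR5, encoded by Gpbar1, is a cell-surface receptor for bile acids that couples to G proteins and raises cAMP, and INT-777 is a synthetic bile acid derivative that activates it. The cells came from mice that carry a green fluorescent protein reporter in Lgr5, a receptor for R-spondin that marks the stem cells at the crypt base. On each of 3 days, cells with high reporter signal were sorted from the intestines of 4 mice, pooled, and set in Matrigel, about 200000 cells in all with 20000 per 10 µL drop. The medium held the Notch ligand peptide JAG-1 at 1 µM and the GSK3 inhibitor CHIR99021 at 3 µM. Cultures received INT-777 at 30 µM or its solvent DMSO 4 h after embedding. The length of the treatment is given as 12 h in the sample labels and as 16 h in the design text, and the counts cannot settle which is right. Total RNA was sequenced as read pairs of 100 nt on a BGISEQ-500. There were 3 INT-777 and 3 DMSO libraries, 1 of each per day, and the replicate number is the day.

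The 6 libraries held between 45682340 and 47905087 read pairs assigned to genes, with 23051 to 23789 genes detected per library. RNA integrity numbers ran from 8.7 to 9.6, and both day 3 libraries had the lowest value of their group, 8.7 for DMSO and 9.0 for INT-777. Day 3 stood apart from the other days along the first principal component, which held 52.1% of the variance, and the treatment groups lay on opposite sides of 0 along the second, with 22.7%. Days 1 and 2 were very much alike: the biological coefficient of variation between the DMSO libraries of days 1 and 2 was 1.99%, and between the INT-777 libraries 2.72%, against 19.4% between the DMSO libraries of days 1 and 3. They were kept as separate replicates because the labels give them separate days. Their counts differed by more than counting noise, with a mean chi-square per gene of 2.44 for DMSO and 3.236 for INT-777, which separate preparations of 1 sample would also show, so it is no evidence of independence.

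**Figure D1:**
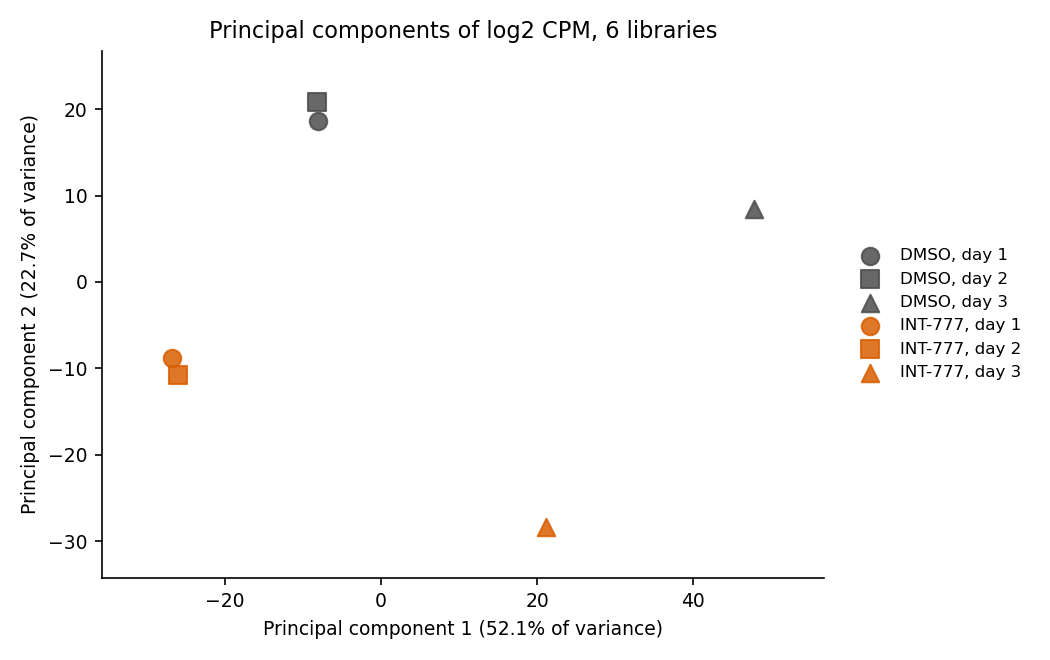
Principal components of log2 CPM over 15998 genes, with component 1 (52.1% of the variance) on the x axis and component 2 (22.7%) on the y axis; each point is 1 library, coloured by treatment, with the marker showing the day. The day 3 libraries lie to the right of all others, and DMSO libraries lie above INT-777 libraries.

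Gpbar1, the gene of the receptor that INT-777 targets, was close to undetected. It lies on chromosome 1 at 74278550 to 74279624 (GRCm38) and had 4, 0 and 5 read pairs in the DMSO libraries of days 1, 2 and 3, and 4, 1 and 4 in the INT-777 libraries. The 9 counts in each group gave an INT-777 over DMSO ratio of 0.968, with an exact 95% interval from counting error alone of 0.340 to 2.75, and the gene was too low to enter the test. Lgr5 itself (chromosome 10, 115450311 to 115587780, overlapped by an antisense gene) was abundant in both groups, at 69.7 ± 6.57 CPM (mean and SD, n = 3) with DMSO and 61.8 ± 7.18 with INT-777. Its log2 fold change of −0.17 ± 0.10 (SE) did not pass the test (edgeR adjusted p = 0.447), whereas with the day as a block the same value, −0.17 ± 0.05, did (edgeR adjusted p = 0.0133).

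Among the large changes with INT-777 were falls of Nos2 and Tnf, which act in inflammation, and rises of Msln and Egr1. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), fell from 37.9 ± 5.4 to 3.8 ± 0.487 CPM, 9.98-fold, with a log2 change of −3.32 ± 0.14 (edgeR adjusted p = 0.00039). The cytokine gene Tnf (chromosome 17, 35199381 to 35202007) fell 4.26-fold, from 3.84 ± 0.596 to 0.898 ± 0.124 CPM (log2 −2.09 ± 0.19, edgeR adjusted p = 0.00584). Msln, which encodes the surface protein mesothelin (chromosome 17, 25748613 to 25754378), rose 5.9-fold, from 15.4 ± 2.07 to 90.9 ± 12.4 CPM (log2 2.56 ± 0.13, edgeR adjusted p = 0.00136). Egr1, an immediate-early transcription factor (chromosome 18, 34859823 to 34864984), rose 5.01-fold, from 20.6 ± 3.9 to 103 ± 10.9 CPM (log2 2.32 ± 0.15, edgeR adjusted p = 0.00368).

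In all, 110 genes were higher and 122 lower with INT-777 among 15998 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05, two-sided). Of these 232 genes, 227 are protein coding, 57 changed at least 2-fold (24 higher, 33 lower), and all 232 differed in the same direction on all 3 days, which the test itself selects for. Of all tested genes 52.0% did so. Chance gives 25% if the days were independent, but days 1 and 2 were so alike that the chance rate here is higher. The 52.0% is therefore no measure of a treatment effect. The other large rises were those of the endocytic receptor Lrp2 (log2 1.92 ± 0.18), the exonuclease Trex2 (1.79 ± 0.17), the interleukin 1 receptor antagonist Il1rn (1.68 ± 0.15), the collagen IV chain Col4a1 (1.33 ± 0.15), the aryl hydrocarbon receptor repressor Ahrr (1.27 ± 0.12) and Pear1 (1.26 ± 0.16). Col4a1 adjoins and overlaps Col4a2 on the other strand, and Pear1 overlaps Insrr, so part of their reads could not be told from those of the neighbour in these unstranded counts. The other large falls were those of the lectin-like genes Clec2e (log2 −2.53 ± 0.15) and Clec2h (−1.97 ± 0.25), Ms4a18 (−2.20 ± 0.15), the alcohol dehydrogenase Adh6a (−1.86 ± 0.23), Cytip (−1.80 ± 0.15) and the xenobiotic-metabolising cytochrome Cyp3a11 (−1.77 ± 0.22). Clec2e, Clec2h, Adh6a and Cyp3a11 belong to families of similar genes, and reads that matched several family members equally well had been left out of the counts. With the day as a block, 1770 genes were higher and 1645 lower, among them 231 of the 232, and the median absolute log2 change of the called genes was 0.26 instead of 0.57. Counts of list members called with the block are to be set against these shares of the 15998 genes, which some lists barely exceed or do not reach. The count depended on single libraries: it was 14, 19, 8 and 9 genes without DMSO replicate 1, DMSO replicate 2, INT-777 replicate 1 and INT-777 replicate 2, and without both libraries of day 1, day 2 and day 3 it was 0, 3 and 4292 (edgeR; without day 1, 1189 genes had an unadjusted p under 0.05 and no other tool was run).

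**Figure D2:**
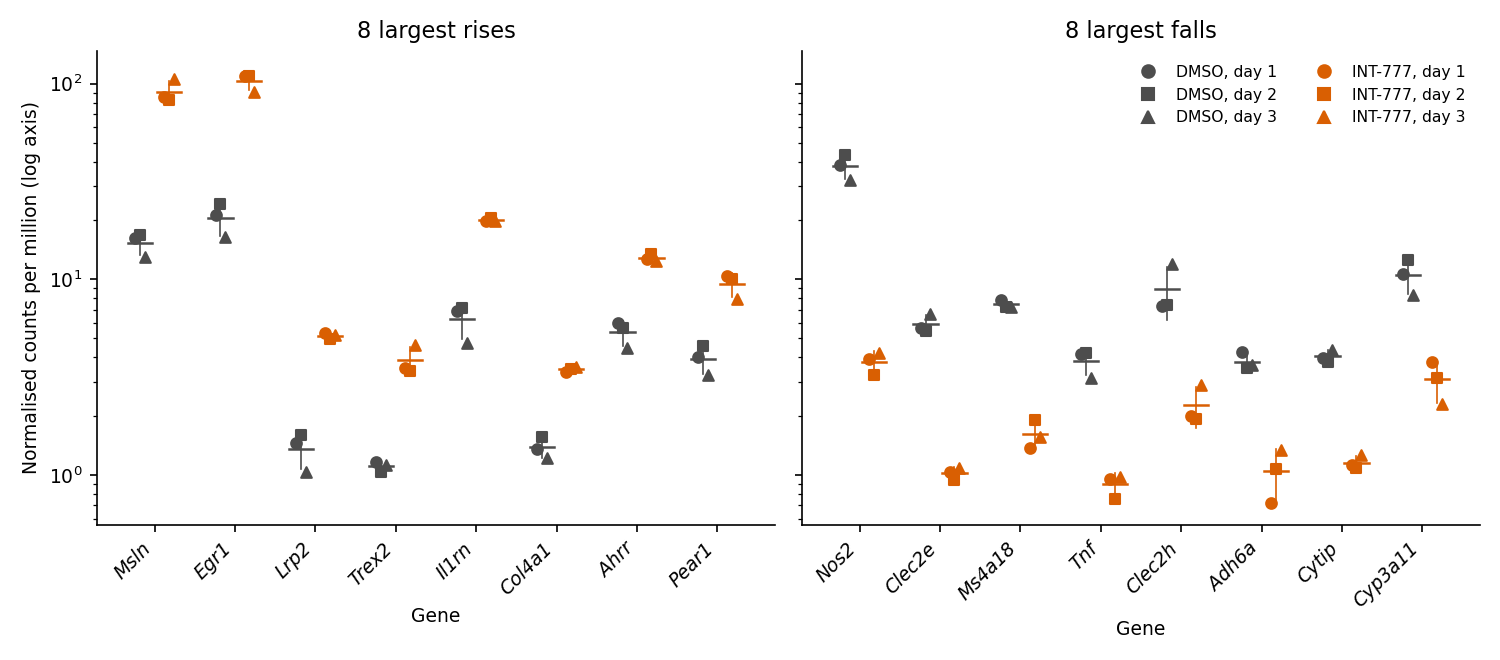
Normalised CPM (log y axis) of the 8 largest rises and 8 largest falls (x axis) in each of the 6 libraries; grey is DMSO, orange INT-777, the marker shows the day, the horizontal line is the group mean and the vertical line 1 SD (n = 3). Nos2 lay between 3.3 and 4.2 CPM with INT-777 and between 32.2 and 43 CPM with DMSO.

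Without the day block, genes of the NF-kB and inflammatory response formed the clearest group. Of its 20 tested members, 10 fell and none rose, and the median log2 change was −0.46. Those that fell were the NF-kB inhibitors and feedback regulators Nfkbia (log2 −0.79 ± 0.06, from 56.6 ± 1.67 to 32.6 ± 1.45 CPM), Tnfaip3 and Tnip1, the NF-kB subunits Nfkb2 and Relb, the kinase Ikbke, the adhesion molecule Icam1, and the cytokines Tnf, Ccl20 (log2 −2.51 ± 0.21, from 2.06 ± 0.0912 to 0.36 ± 0.0728 CPM) and Csf1 (log2 −1.52 ± 0.21). In counts adjusted over the list alone, 12 members were lower and 2 higher, and with the day as a block 14 were lower and 2 higher, the latter being Sod2 and Ptgs2. The list was lower as a set (camera adjusted p = 1.14e-14 over 38 lists). It was the single list that stayed called with an estimated correlation (camera adjusted p = 0.0473). With the day block and the preset correlation, its camera adjusted p was 2.89e-15, and that of goblet markers was lower, 7.42e-73. With the day block and an estimated correlation no list was called, and the lowest camera adjusted p was 0.369, the value of the NF-kB list. That fit also missed the list changed in simulated data, drawn a single time, so its power in that setting may have been low. The simulated list had 25 genes drawn independently and shifted 1.23-fold, and power for the NF-kB list was not tested. The call therefore did not hold in every fit. Summed CPM of 35 immune cell markers was near 2 in all day 1 and day 2 libraries, and 15.9 (DMSO) and 12.8 (INT-777) on day 3.

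**Figure D3:**
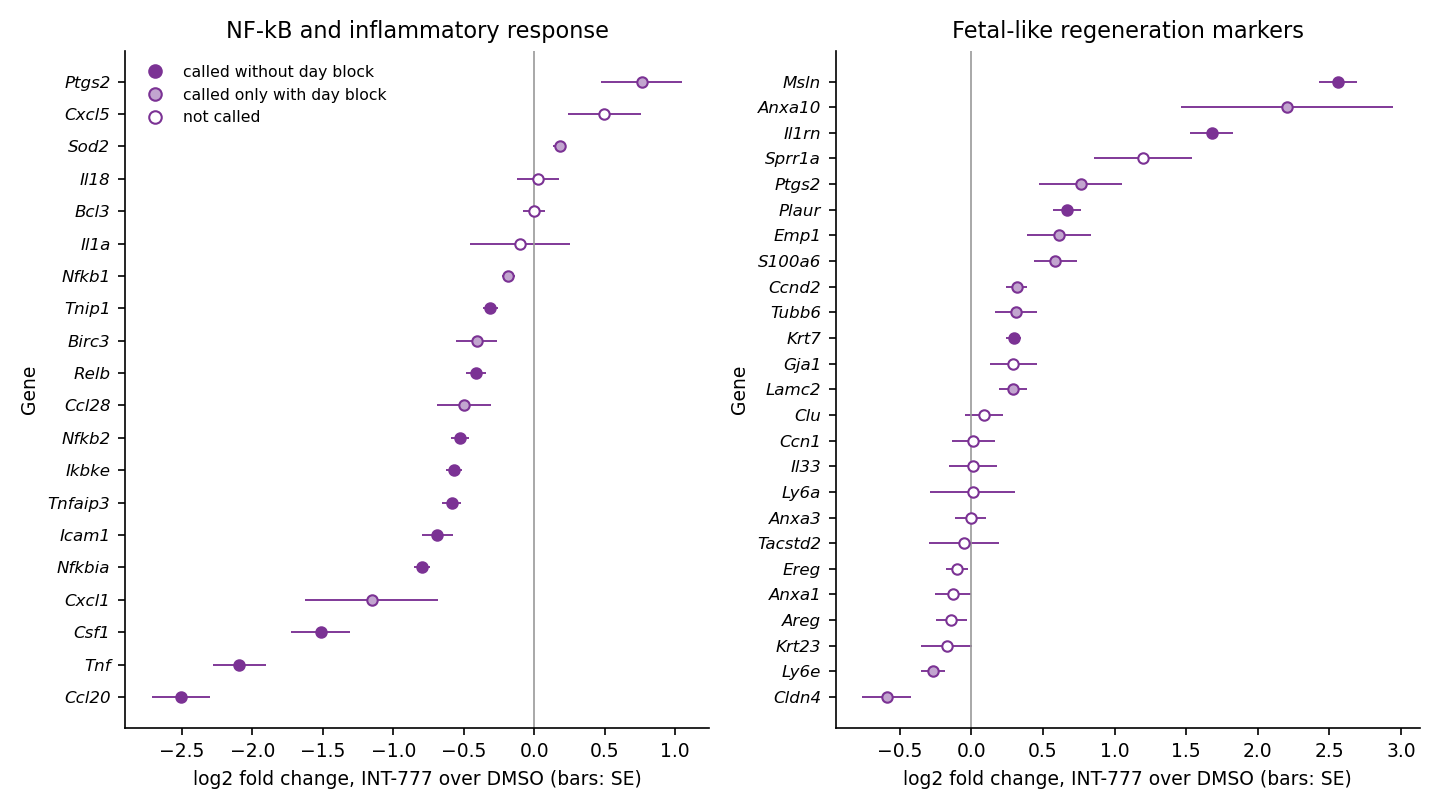
Log2 fold change of INT-777 over DMSO (x axis; bars are standard errors) for each tested member (y axis) of the NF-kB list (20 genes) and of the fetal-like list (25 genes). Dark points passed the test without the day block, light points only with it and open points neither; in the NF-kB list 10 genes are dark and all of them lie below 0.

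The interferon list and the antigen presentation list were also lower. Of 26 tested interferon response genes 1 fell, Ddx58, the RNA sensor RIG-I (log2 −0.44 ± 0.07, edgeR adjusted p = 0.0398), with a list median of −0.30. The number lower was 3 adjusted over the list alone and 11 with the day block. Oasl2 had a log2 change of −0.95 ± 0.20 and Xaf1 of −1.10 ± 0.28, and neither passed without the block. As a set the list had a camera adjusted p of 3.84e-05, and the adjusted p was 0.323 with an estimated correlation. All 13 genes of antigen presentation had negative log2 changes (median −0.33). Those of smallest p, not of largest change, were B2m (−0.48 ± 0.09), H2-Q2 (−0.43 ± 0.09) and H2-Ab1 (−0.35 ± 0.10). None of the 13 passed over all genes, 3 did adjusted over the list alone, and 7 did with the day block. Tested together they gave a camera adjusted p of 0.000947, with an adjusted p = 0.236 with an estimated correlation. H2-Q2 is one of a family of near-identical genes, so its count is uncertain.

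Markers of the fetal-like state that crypts take on during regeneration were higher as a set, through few of their members. Msln, Il1rn, Plaur, the urokinase receptor (log2 0.67 ± 0.10), and Krt7, a simple-epithelium keratin (0.29 ± 0.05), rose among 25 tested, and none fell. Adjusted over the list alone 7 were higher and 2 lower, and with the day block 11 were higher and 2, Cldn4 and Ly6e, lower. Without both libraries of day 3 the fetal-like list held 11 higher and 8 lower members, with a median of 0.20, and without day 1 none passed (edgeR). The commonly used markers Ly6a (log2 0.01 ± 0.30), Anxa1 (−0.13 ± 0.13) and Clu (0.09 ± 0.13) did not pass in either fit. The list median was 0.29 and the camera adjusted p was 1.01e-05, with an adjusted p = 0.323 with an estimated correlation. The related list of crypt genes induced by damage was not called (camera adjusted p = 0.125): Msln, Il1rn, Krt7 and Sprr2a3 rose, whereas Nos2 and the chemokine Cxcl16 fell.

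Feedback genes of EGFR and ERK signalling were higher too. Egr1, the ERK phosphatase Dusp5 (log2 0.65 ± 0.10, from 24.2 ± 3.01 to 37.9 ± 1.87 CPM) and Phlda1 (0.42 ± 0.07) rose among 28 tested members, and none fell. The number higher was 6 adjusted over the list alone and 14 with the day block, and without day 3 it was 14, with 3 lower. For the ERK list the camera adjusted p was 6.41e-07, with an adjusted p = 0.323 with an estimated correlation. The list of dissociation and heat shock genes, kept as a sign of cell stress, was called higher (camera adjusted p = 0.00269, and adjusted p = 0.384 with an estimated correlation), and it shares Egr1 with the ERK list. In it the immediate-early genes Egr1, Fos (log2 0.70 ± 0.07) and Junb rose, and Jun (−0.63 ± 0.08) and Atf3 (−0.98 ± 0.15) fell, out of 25 tested. With the day block 12 of its members were higher and 6 lower.

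Genes that respond to cAMP and CREB, the classical output of a receptor coupled to the stimulatory G protein, moved both ways. Egr1, Fos and Junb rose and Atf3 fell among 31 tested, the list median was −0.14, and the list was not called (camera adjusted p = 0.309). With the day block 5 were higher and 9 lower. The cAMP-induced genes Nr4a2 (log2 −0.37 ± 0.07), Pde4b (−0.60 ± 0.16) and Nr4a3 were among those lower. The 5 that were higher were Egr1, Fos, Junb, Cebpb and Nr4a1. RNA was taken at a single time, 12 or 16 h into the treatment, so an earlier response of these genes could have been missed. Targets of YAP, TAZ and TEAD were not called either (camera adjusted p = 0.318, median 0.02). Among the 28 tested, F3, the gene of coagulation tissue factor, rose from 44.1 ± 4.15 to 75.9 ± 5.33 CPM (log2 0.78 ± 0.08), and so did the transcription factor Tead4 (0.56 ± 0.08). With the day block, 6 were higher and 4 lower.

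Stem cell markers were slightly lower as a set. Smoc2 (log2 −0.45 ± 0.05, from 226 ± 10.9 to 165 ± 3.19 CPM) and Clca3b (−0.66 ± 0.09) fell among 28 tested members, with a list median of −0.15, and 22 of the 28 had negative log2 changes. There were 4 lower members adjusted over the list alone. With the day block 14 were lower, Olfm4 and Lgr5 among them, and 4 higher, namely Ephb2, Cdk6, Cdca7 and Ascl2. The camera adjusted p was 9.41e-05, with an adjusted p = 0.323 with an estimated correlation. Targets of Wnt signalling did not separate in one direction: none of 24 passed, the Wnt feedback gene Axin2 had a log2 change of −0.19 ± 0.05 and the transcription factor Sox9 of −0.16 ± 0.05, and the list was not called (camera adjusted p = 0.676). In the fit with the day block, 6 Wnt targets were higher and 9 lower. In the Notch list the ligand gene Jag2 rose (log2 0.69 ± 0.10), the log2 change of Jag1 was 0.21 ± 0.07, 1 of 18 passed, and the list was not called (camera adjusted p = 0.624, median −0.01 although the test statistic was positive). Under the day block 3 Notch genes were higher and 5 lower.

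Genes of DNA replication were slightly higher. None of the 42 tested S phase genes passed over all genes or over the list alone, but 39 had positive log2 changes with a median of 0.13, and 17 were higher and none lower with the day block. The values were largest in evidence for Rad51ap1 (log2 0.22 ± 0.05) and for the ribonucleotide reductase subunit Rrm2 (0.31 ± 0.08). The camera adjusted p was 1.01e-05, with an adjusted p = 0.522 with an estimated correlation. Of the 53 genes of G2 and M phase, 47 had positive log2 changes, with a median of 0.06. Cks1b (log2 0.19 ± 0.07) and Rangap1 (0.19 ± 0.08) had the smallest p without the block. None passed without the block and 9 were higher with it. That list was called higher (camera adjusted p = 0.0209, and adjusted p = 0.732 with an estimated correlation). The call was lost without INT-777 replicate 1 (camera adjusted p = 0.169), INT-777 replicate 2 (0.165) or both libraries of day 3 (0.306). Without DMSO replicate 3 it was lost with the direction turned (0.1835). That last fit holds day 3 in the INT-777 group alone, and 34 of the 53 differed between days, all lower on day 3.

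Markers of goblet cells, the mucus-secreting lineage, were lower with INT-777 on every day. All 25 had negative log2 changes, with medians of −0.89, −0.87 and −0.91 on days 1, 2 and 3, and −0.89 in the fit of all libraries. The summed marker level was 6323 and 3425 CPM (DMSO and INT-777) on day 1, 6236 and 3328 on day 2, and 30559 and 13710 on day 3. None of the 25 passed the test without the day block, in either adjustment: the main mucin gene Muc2 had a log2 change of −1.75 ± 0.63 (edgeR adjusted p = 0.28) and Ramp1 of −2.32 ± 0.76 (edgeR adjusted p = 0.232). With the block 23 of the 25 were lower, Ramp1 among them (−2.26 ± 0.19, edgeR adjusted p = 1.09e-06) and Muc2 not (edgeR adjusted p = 0.0907). The list was called (camera adjusted p = 0.000171), but its estimated correlation was 0.98. The camera adjusted p was 0.568 with an estimated correlation and 0.369 with that and the day block (a fit that called no list). Without DMSO replicate 3 the call was lost (camera adjusted p = 0.1495). That last fit holds day 3 in the INT-777 group alone, and 24 of the 25 markers were higher on day 3.

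**Figure D4:**
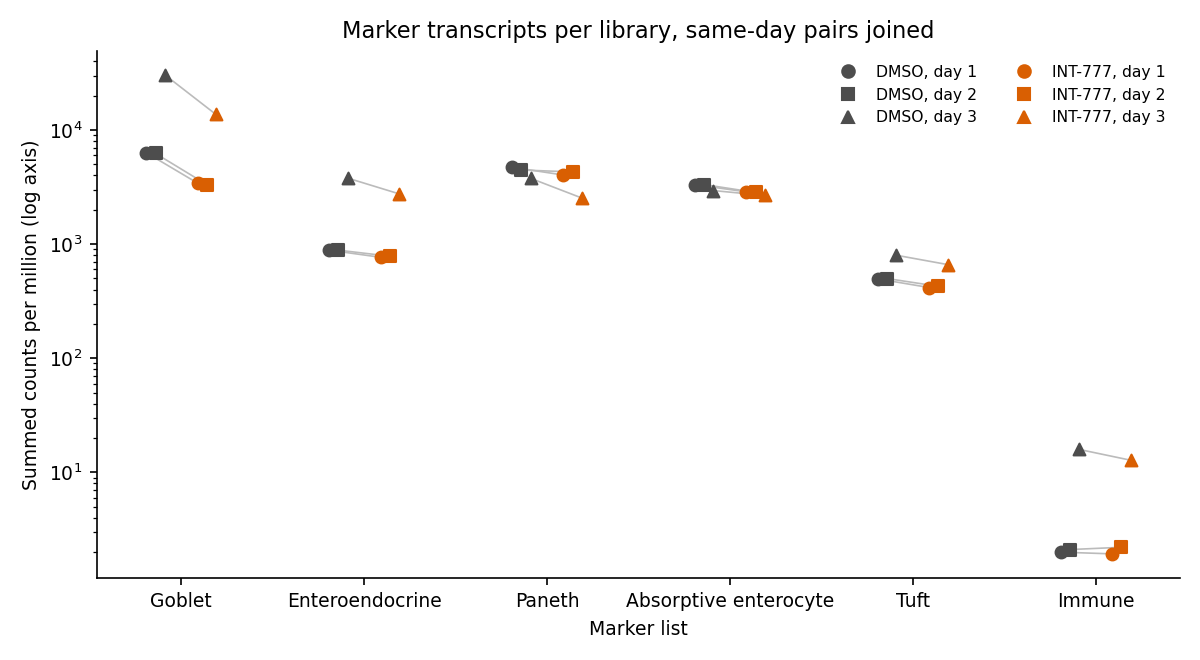
Summed CPM (log y axis) of 6 marker lists (x axis) in each library, with the DMSO (grey) and INT-777 (orange) library of the same day joined by a line and the marker showing the day. Goblet totals were lower with INT-777 on all 3 days, and both day 3 libraries held more goblet, enteroendocrine, tuft and immune transcripts than the other libraries.

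Other differentiated lineages moved less. Paneth cell markers were called lower (median −0.25, camera adjusted p = 0.000288, and adjusted p = 0.323 with an estimated correlation), with Habp2 (log2 −1.32 ± 0.20) as the single gene of 20 that fell over all genes and over the list alone. The log2 change of Pla2g2a was −0.60 ± 0.16, 9 were lower with the day block, and the call was lost without INT-777 replicate 3 (camera adjusted p = 0.0519). Absorptive enterocyte markers were called lower (median −0.20, camera adjusted p = 0.0325, and adjusted p = 0.323 with an estimated correlation), and 3 of 34 fell, the peptidase genes Dpp4 (log2 −0.35 ± 0.06) and Anpep (−1.66 ± 0.25) and Cyp3a11. Adjusted over the list alone 6 were lower and 4 higher, with the day block 14 were lower and 6 higher, and the call was lost without DMSO replicate 1 (0.0903), DMSO replicate 2 (0.0943), INT-777 replicate 1 (0.0581) or both libraries of day 1 (0.0819). Enteroendocrine markers were not called without the block (camera adjusted p = 0.966) and were lower with it (0.047, and adjusted p = 0.576 with an estimated correlation, in a fit that called no list). None of 30 passed without the block, and with it 2 were higher, Pyy (0.76 ± 0.15) and Ghrl, and 9 lower, among them Reg4 (−1.29 ± 0.07). Without DMSO replicate 3 this list was called in the other direction, higher (camera adjusted p = 0.0007239). That fit has no block and holds day 3 in the INT-777 group alone, and 27 of 30 markers were higher on day 3. The call therefore mixes the day with the treatment. Summed enteroendocrine markers were lower with INT-777 on each day (log2 −0.207, −0.175 and −0.457), while the list medians were −0.03, 0.05 and −0.12. On day 1 the sum was 886 CPM with DMSO and 767 with INT-777, and Reg4 alone 133 and 54.6. On day 2 the sums were 885 and 784, and Reg4 alone 119 and 57.4. A large part of the fall in the sum on those days was thus that of Reg4. Tuft cell markers were not called (camera adjusted p = 0.891): none of 20 passed, and the log2 changes were 0.22 ± 0.08 for the lineage factor Pou2f3 and −1.12 ± 0.43 for Plcb2. With the block 1 tuft marker was higher and 2 lower.

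The bile acid receptor FXR is a further sensor of bile acids, and the list of its targets was lower as a set. The list was not split into genes that FXR raises and genes that it lowers, so its direction does not measure FXR activity. The log2 changes of its members were negative for 10 and positive for 3, with a median of −0.26. Of 13 tested, the bile acid importer gene Slc10a2 (log2 −1.04 ± 0.15, from 2.85 ± 0.23 to 1.38 ± 0.0986 CPM) and Cyp3a11 fell and Fetub rose. Adjusted over the list alone 3 were higher and 6 lower, the same counts as with the day block, in which the FXR-induced genes Fgf15 (−0.26 ± 0.07) and Nr0b2 (−1.23 ± 0.35) were lower and the bile acid exporter gene Slc51a (0.78 ± 0.14) was higher. The camera adjusted p was 0.0213, with an adjusted p = 0.323 with an estimated correlation, and the call was lost without INT-777 replicate 1 (camera adjusted p = 0.0588).

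Genes of lipid synthesis were lower by a small margin. Of 26 sterol biosynthesis genes 24 had negative log2 changes (median −0.13); Pmvk (log2 −0.45 ± 0.05, from 58.1 ± 1.4 to 42.5 ± 1.46 CPM) fell over all genes, 8 were lower adjusted over the list alone, and 11 with the day block. The next in evidence were Acat2 (−0.29 ± 0.05) and Mvd (−0.27 ± 0.05). The camera adjusted p was 2.52e-07, with an adjusted p = 0.062 with an estimated correlation, and the directional fry test also called it (adjusted p = 0.000871). Among 16 fatty acid synthesis genes, the acetyl-CoA synthetase gene Acss2 (−0.33 ± 0.06) and the desaturase gene Fads1 (−0.30 ± 0.05) fell, and the change of Fads2 was −0.33 ± 0.07. Adjusted over the list alone 5 were lower, with the block 8 were lower and 1 higher, and the camera adjusted p was 0.000444, with an adjusted p = 0.323 with an estimated correlation.

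Housekeeping programmes showed shifts of under 0.2 on the log2 scale. All 51 cytosolic ribosomal protein genes had positive log2 changes (median 0.12), among them Rpl13a (0.27 ± 0.05) and Rpl30 (0.13 ± 0.04). None passed over all genes or over the list alone, and 20 were higher with the day block (camera adjusted p = 4.96e-08, and adjusted p = 0.563 with an estimated correlation). On day 1 their median was 0.01, against 0.17 and 0.16 on days 2 and 3. Nuclear genes of oxidative phosphorylation had a median of 0.05, with 0 of 44 passing without the block and 7 higher with it, among them Ndufs7 (0.18 ± 0.05), Uqcrfs1 (0.13 ± 0.04) and Ndufa8 (0.15 ± 0.05). Their camera adjusted p was 0.00588, with an adjusted p = 0.568 with an estimated correlation, and the call was lost without DMSO replicate 2 (0.0509), INT-777 replicate 3 (0.188), both libraries of day 2 (0.129) or both of day 3 (0.318). Mitochondrially encoded genes were called lower (median −0.12, camera adjusted p = 0.0361, and adjusted p = 0.563 with an estimated correlation), and not with the day block (0.1235). That call was also lost without DMSO replicate 1 (camera adjusted p = 0.1217), DMSO replicate 2 (0.2701), INT-777 replicate 1 (0.0945), INT-777 replicate 2 (0.056), both libraries of day 1 (0.2268) or both of day 2 (0.3812). None of their 15 members passed in either fit of all 6 libraries, 10 were lower without day 3, and the values were −0.12 ± 0.05 for mt-Co1, −0.12 ± 0.06 for mt-Nd4 and −0.83 ± 0.29 for mt-Atp8, which overlaps mt-Atp6. In the unfolded protein response list Atf3 and Chac1 (log2 −0.80 ± 0.13) fell out of 28, and Trib3 had a change of −0.56 ± 0.15. With the block 8 were lower and 1 higher. That list was called lower (median −0.10, camera adjusted p = 0.00588, and adjusted p = 0.568 with an estimated correlation), and not without DMSO replicate 3 (0.166).

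**Figure D5:**
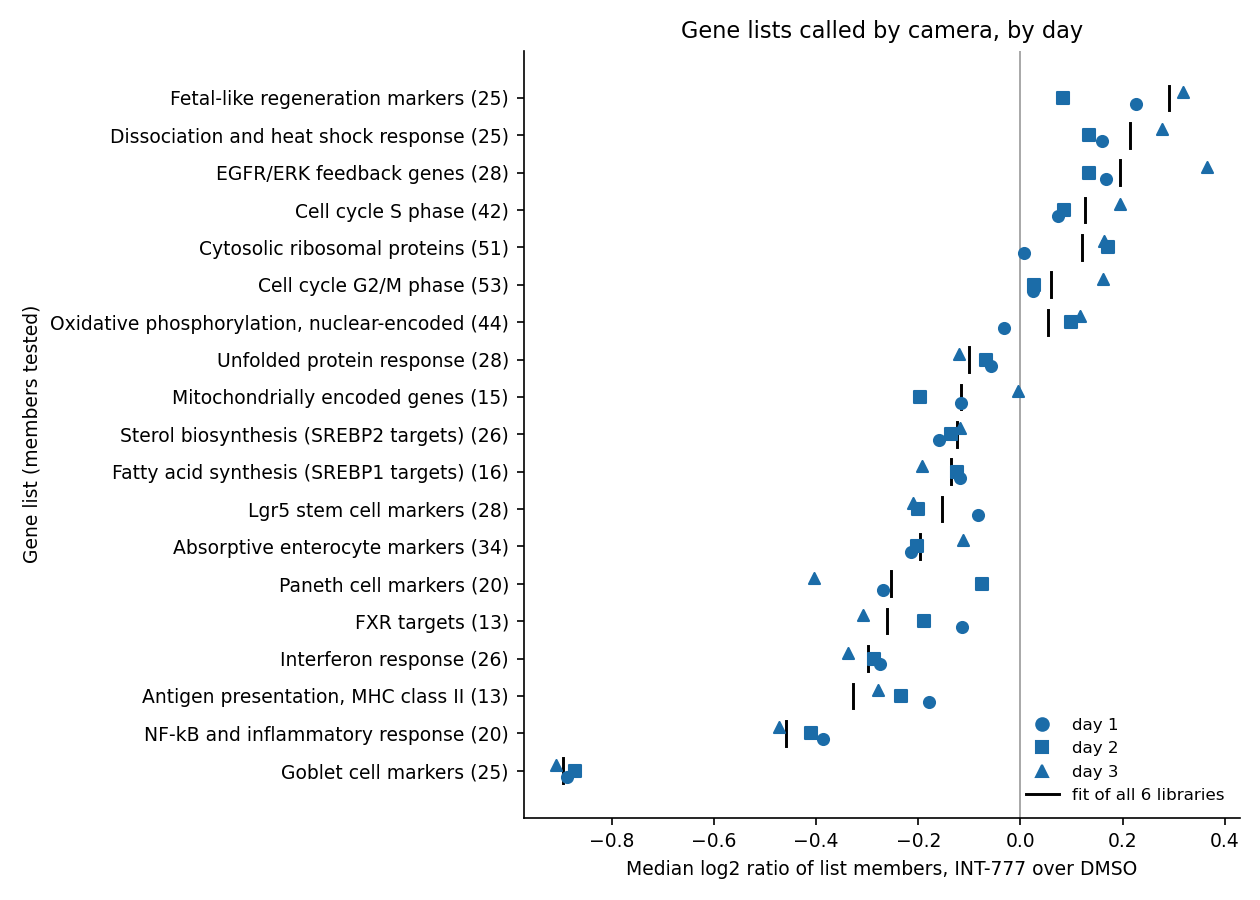
Median log2 ratio of INT-777 over DMSO (x axis) for each of the 19 gene lists called by camera (y axis, with the number of members tested). Points are the same-day ratios with the marker showing the day, and the vertical bar is the median of the fitted changes over 6 libraries; goblet markers lie near −0.9 on all 3 days and most other lists within 0.5 of 0.

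Of 38 lists tested, 19 were called by camera, 7 higher and 12 lower. Without the day block the directional fry test called 6 lists. Of these, 4 were also called by camera in the same direction: NF-kB, sterol biosynthesis, antigen presentation and FXR targets. Fry also called glycolysis and hypoxia genes higher (adjusted p = 0.0342) and mesenchymal markers lower (adjusted p = 0.0474), which camera did not call. With the day block the directional fry test called NF-kB and sterol biosynthesis (adjusted p = 0.0177 each) and antigen presentation (0.0216). It also called fatty acid synthesis and interferon genes (0.0464 each) and goblet markers (0.0482). FXR targets (0.0663), glycolysis and hypoxia genes (0.0663) and mesenchymal markers (0.0964) were then not called. Not called without the day block, with their camera adjusted p, were targets of LXR (0.0616), glycolysis and hypoxia genes (0.0815), p53 targets (0.15) and lysosome genes (0.173), all 4 of which were called with it (0.0181, 0.0266, 0.0235 and 0.0266). With an estimated correlation none of these 4 was called in either fit. The camera adjusted p was then 0.522, 0.323, 0.563 and 0.756 without the block, and 0.556, 0.441, 0.556 and 0.556 with it. The blocked fit with that estimate called no list and missed the list changed in simulated data. The 4 calls thus rest on the preset correlation. Neither fit called Src kinases and focal adhesion (0.0963), targets of NRF2 (0.325, median 0.11 but mean −0.06), xenobiotic response genes (0.394), TGF-beta and BMP targets (0.4), or PPAR targets and fatty acid oxidation (0.624, median 0.01 but mean −0.02). Within the xenobiotic list Ahrr and Cyp1a1 rose and Cyp3a11 and Ces2c fell. Among lists of other cell types, mesenchymal (0.0616), neural (0.318) and endothelial (0.325) markers were not called, and the immune list had 4 tested members, too few for the test.

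The days themselves differed in the expression of lineage marker genes. Expression differed between days for 3273 genes, 20.5% of those tested (edgeR F-test of the day terms with treatment in the model, adjusted p under 0.05), and 1896 of these were higher and 1377 lower on day 3 than on days 1 and 2. Goblet and enteroendocrine genes led: Zg16 had 189 CPM on days 1 and 2 and 1187 on day 3, Fcgbp 2515 and 13430, and the enteroendocrine granule gene Chga 75.5 and 309.8, each with 4 and 2 libraries. Of 25 goblet markers 24 differed between days and all 24 were higher on day 3, as were 27 of 30 enteroendocrine markers and the 9 of 20 tuft markers that differed. Among 53 genes of G2 and M phase 34 differed between days, and all were lower on day 3. The sums for immune markers were 2.00 and 2.11 CPM (DMSO, days 1 and 2) against 15.9 on day 3, and for mesenchymal markers 12.6 and 12.0 against 34.3. Without DMSO replicate 2 the number of genes that differed between days was 2010.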

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

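The number of genes higher and lower with INT-777 (110 and 122) stayed within 1.5 times under median-ratio factors, upper-quartile factors, limma-voom, a stricter filter and the counts of 1 strand. It moved to 1770 and 1645 with the replicate block (the day), 369 and 429 with DESeq2, 1112 and 1162 with DESeq2 and the block, 186 and 249 with no low-count filter, 1153 and 883 with RNA integrity as a covariate, 1715 and 1720 with a GC offset and the block, 18 and 19 at an adjusted p under 0.01, and 234 and 248 under 0.10. In fits chosen after seeing the data it was 1938 and 1915 with the block on days 1 and 2 alone, and 1275 and 1419 with the block and days 1 and 2 summed. With libraries or days left out it ran from 0 (without day 1) to 2225 (without day 3) for genes higher and from 0 to 2067 for genes lower. For the move with the block a test stands under the observations and leaves the cause open; for the other moves the cause was not tested. No called gene changed sign in any setting.

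Of 38 lists 19 were called by camera without the block, against 1 with an estimated correlation and 6 with directional fry. The block lost the mitochondrially encoded list and gained 5 (enteroendocrine, LXR, glycolysis, p53 and lysosome); beyond the changes printed in the report it changed no other list call. Of 69 named genes the block lost 0 calls and gained 27, and leaving out day 1 lost 36. With the block and days 1 and 2 summed, 25 were gained and 0 lost. With libraries or days left out, the adjusted p of the G2 and M phase list ran from 0.0001961 to 0.3057, and its direction reversed without DMSO replicate 3 (0.1835); that of the enteroendocrine list ran from 0.0007239 to 0.9631 and its direction reversed in the same setting (0.0007239). Leaving out 1 library in a fit with no block holds its day in 1 group alone, so such fits mix the day with the treatment. How much of each change this explains was not tested. The number of genes that differ between days (3273) was 2447 to 4140 with other tools, factors and no filter, and 2010 (without DMSO replicate 2) to 4867 (without INT-777 replicate 3) with libraries left out.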

Other observations

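Among 12 gene families chosen after the data were seen, so not independent evidence, targets of the aryl hydrocarbon receptor stood out: Cyp1a1 (log2 0.44 ± 0.06, from 113 to 153 CPM), Aldh3a1 and Ahrr rose among 6 tested, and all 6 were higher with the day block (camera adjusted p = 2.352e-08, and adjusted p = 0.0444 with an estimated correlation). Genes of the basement membrane rose in part: the nidogen gene Nid1 and the collagen IV genes Col4a1 and Col4a2, 3 of 15 (camera adjusted p = 0.0174, and adjusted p = 0.163 with an estimated correlation). Of 18 genes of S100 proteins and annexins, S100a14, S100a16, Anxa8 and Anxa2 rose (camera adjusted p = 2.53e-06, and adjusted p = 0.282 with an estimated correlation). With the day block 7 were higher and 1 lower, and S100a14 did not pass (edgeR adjusted p = 0.0527). The keratin genes Krt7 and Krt18 rose among 16, and that family was not called without the day block (camera adjusted p = 0.183) and was higher with it (0.0231), with 5 members higher and 1 lower; the adjusted p was 0.474 with an estimated correlation and no block.

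Among families that were lower, Gstm3 fell out of 21 glutathione S-transferase genes, and 12 were lower and 1 higher with the day block (camera adjusted p = 4.466e-05, and adjusted p = 0.377 with an estimated correlation). The tight junction gene Cldn3 fell out of 12 claudins (camera adjusted p = 0.00359, and adjusted p = 0.231 with an estimated correlation), and the membrane mucin Muc4 out of 6 mucins (camera adjusted p = 0.0112, and adjusted p = 0.313 with an estimated correlation). Clec2e and Clec2h fell out of 6 C-type lectin 2 and guanylate-binding genes (camera adjusted p = 2.53e-06, and adjusted p = 0.072 with an estimated correlation). Of 4 butyrophilin-like genes Btnl4 fell (log2 −0.53, edgeR adjusted p = 0.0466), and all 4 were lower with the day block. As a set they were lower (camera adjusted p = 0.0001863, and adjusted p = 0.072 with an estimated correlation). The minimum of 5 members was not applied to the families. Tubulins, dual specificity phosphatases and histones were not called.

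The tests below on immune cells, on the share of goblet cells and on FXR were chosen only after the result was seen; the predictions of the others were written before. Among the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 split that called at least as many genes (232; all others called 0). The other splits put the treatment difference into the spread, so low counts there are no test of excess calls, and 10 splits cannot show a chance under 0.05. For lists, 2 of the 10 splits, the real one included, called at least 19. The other of these put both day 3 libraries on 1 side, so it also measures the day. The 3 other splits that part all 3 same-day pairs called 9, 10 and 8 lists (10, 10 and 9 with the block, against 23 for the real one); these still hold part of the treatment difference, so they do not tell how many calls chance gives.

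More genes were called with the day block than without it. Without the day 3 libraries the fit with no block called 4292 genes, which a wide spread between day 3 and the rest predicts, and so does the near-identity of days 1 and 2. With the labels exchanged within 1 day the blocked fit called at most 0 genes, against 3415; that exchange moves the treatment difference into the spread, so it cannot show whether the 3415 calls are too many. Days 1 and 2 were so alike that the counts with and without the block, 3415 and 232, may rest on fewer than 3 independent days; with those days summed the blocked count was 1275 higher and 1419 lower.

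NF-kB and inflammatory genes were lower with INT-777. The summed immune marker level had a mean log2 ratio of −0.09901 over the days, against a list median of −0.4584, which decided nothing by the rule. On days 1 and 2 the immune ratios were −0.050 and 0.066, while the NF-kB medians were −0.386 and −0.410. With immune sums of only about 2 CPM these ratios rest on few read pairs, and their counting error was not worked out. They therefore do not decide whether fewer immune cells contributed on those days. On day 3 the values were −0.313 and −0.473, which leaves open whether fewer immune cells contributed there. A GC trend did not account for the call by the rule written beforehand: with a GC offset and the block the list stayed called at the preset correlation (camera adjusted p = 9.139e-16). In the blocked fit without the offset the adjusted p was 0.369 with an estimated correlation, in a fit that called no list.

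Goblet markers were lower with INT-777. Neither a GC trend (camera adjusted p = 1.25e-73 with a GC offset and the block) nor the day 3 libraries alone (median log2 −0.8489 without them) fits as the cause. The first of these values is at the preset correlation, and in the blocked fit without the offset the adjusted p was 0.369 with an estimated correlation, in a fit that called no list. Whether there were fewer goblet cells or less expression per cell cannot be told: all members were lower, but by amounts that differed more than their errors (mean squared standardised deviation 32.27, where a value under 2 was the limit for a common change).

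A hypothesis was that INT-777 also activated FXR, which predicts higher Fgf15, Nr0b2, Slc51a, Slc51b and Fabp6. With the day block 1 of these 5 was higher, Slc51a, Fgf15 and Nr0b2 were lower, Slc51b did not pass and Fabp6 was too low to test, so the prediction was not met. Gpbar1 had 9 counts in each group, and what cells carry the receptor was not tested.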
